A study of Drosophila melanogaster with 6 samples.

How the data were processed

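The study measured RNA in Drosophila S2 cells, a line with macrophage features that was derived from embryos, after RNA interference against Brr2 or under a control treatment. The sample titles carry the prefix sh, whereas the treatment protocol in the labels describes double-stranded RNA added to the medium. There were 6 libraries, 3 per group. Per the labels' protocols, total RNA was depleted of ribosomal RNA before library construction, with a kit whose name refers to ribosome profiling; how that kit was used on total RNA is not given in the sources used here. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

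The deposited table holds estimated counts per gene and per transposon copy, already whole numbers, not scaled between libraries. Trimmomatic, TopHat2 and build BDGP6 are named in the submitters' processing notes, without versions. The counting tool, its treatment of reads with several hits and its use of strand are not given in the sources used here. The value 1 was held by a mean of 965.7 features per library and the value 4 by 438.2, against 368.5 features at 2 and 387.3 at 3, and near-identical transposon copies held nearly equal values, so the values may not be counts of separate reads and copies of repeated genes are reported as uncertain. Genes that overlap, or lie antisense to each other, share the same limit. Totals ran from 127654975 to 147620403 estimated counts per library. If these were counts of separate reads, spread between libraries rather than counting error would set the precision for features at high levels. The file lists 23882 features, of which 17830 are genes, 5571 are transposon copies and 481 are other transcript entries. Positions, intron numbers and biotypes came from the Ensembl release 115 annotation of build BDGP6.54, matched by identifier for 17751 genes; 79 genes had no match. That build is a later release than the name in the notes specifies, and coordinates are those of the annotation.

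Differential abundance was tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, TMM scaling, filterByExpr, no replicate block), with Benjamini-Hochberg adjustment over all 14167 tested features and a threshold of 0.05. Of these, 11590 were genes. Standard errors were taken as the absolute log2 fold change over the square root of F. Levels are TMM-scaled CPM (counts over the scaled library total, at the usual multiple). The 43 gene lists were tested with limma 3.58.1 (camera on log2 CPM, prior count 2, preset correlation 0.01, lists with at least 5 tested members, 2-sided), beside camera with an estimated correlation and fry. Brr2 itself was in no list. Genes were named by a rule set before the data were examined: Brr2, the 12 largest increases and 12 largest decreases among called genes with a mean of at least 5 CPM, no overlap between groups and a proper symbol, the 2 largest each way without the symbol condition, up to 4 members per list by adjusted p, and the members of the lists of U5 and tri-snRNP proteins and of circRNA host genes. The genes snRNA:7SK and RPA2 were added after their values were seen.

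Alternatives were other scalings, DESeq2 1.42.0, limma voom, other filters, a fold threshold, a replicate block and leaving out each library. Sums of transposon families and of histone types, and a fit without rRNA rows, were chosen after seeing the data. Replicate numbers are shared by the groups in the labels. Between libraries of different groups, deviations from the group means correlated at 0.16 to 0.317 for the same number and at -0.229 to 0.051 for other numbers. The labels state no pairing. Deviations cancel within a group, so these correlations depend on each other and are weak evidence that the numbers pair the samples. The reported tests ignore this possible pairing, and the fit with a replicate block for it is given where it changes a call. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom of 113.7 to 1577).

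The test was run on simulated counts for 14167 features with the means, spread and library sizes of this comparison. It recovered 25% of 100 features changed 2-fold and 65% of 100 changed 4-fold, and called 5 unchanged features. No other features were changed, whereas 2385 features passed in the data, so the adjustment was stricter in the simulation. These percentages therefore do not give the power of the reported test. In the same simulation 1 list shifted 2-fold was called and 0 of 20 unshifted lists were, but simulated genes vary independently, which real genes do not. Gene-level values do not separate spliced, unspliced and circular RNA.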

Results

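RNA from S2 cells was compared between 3 libraries from cells under RNA interference against Brr2 and 3 control libraries. Brr2 is the helicase of the U5 snRNP that unwinds U4 from U6 before splicing. The design text asks how widely Brr2 acts on the making of circular RNA, which gene-level values cannot separate from linear RNA. Totals were 127654975 to 147620403 estimated counts per library. Transposon copies held 36.3% ± 0.52 of the counts in the knockdown libraries and 21.8% ± 2.21 in the control libraries (SD, n = 3 each), and protein-coding genes held 48.5% ± 1.05 and 64.9% ± 4.29. The copies of copia alone held 28.2% ± 0.581 and 13.1% ± 1.39, so the rise of the transposon share was that of copia. Its copies may share reads, which leaves these shares uncertain.

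The Brr2 gene, listed as l(3)72Ab (FBgn0263599; BDGP6.54, chromosome 3L, 15960836 to 15967872, minus strand, 5 introns), fell from 192.6 ± 31.9 to 100.8 ± 7.3 CPM (SD, n = 3 each). The log2 fold change was -0.93 (SE 0.155, edgeR adjusted p = 0.0111), which left 52.3% of the control level. All 3 knockdown libraries, at 108.5, 94.0 and 99.8 CPM, lay below the control libraries, at 158.1, 198.5 and 221.1 CPM. An exact 2-sided permutation test of the levels gave p = 0.1, the smallest that 3 against 3 allows. The sample titles carry the prefix sh while the treatment protocol describes double-stranded RNA. If double-stranded RNA was used, carried-over reads would add to the targeted stretch, so the remaining level is uncertain.

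**Figure D1:**
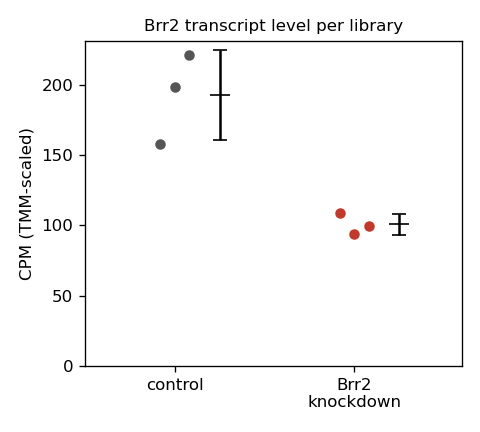
Level of Brr2 in CPM (vertical axis) for each control and knockdown library (points), with the mean and SD of each group (bars). The knockdown libraries lie between 94.0 and 108.5 CPM and the control libraries between 158.1 and 221.1 CPM.

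After Brr2 knockdown, Irbp, Ku80, DNAlig4, RpA-70 and RPA3 rose, while Act5C and the tubulin gene betaTub56D fell. Irbp and Ku80, the subunits of the Ku complex that binds broken DNA ends, rose 3.45-fold and 3.63-fold (log2 1.78, SE 0.17, and 1.86, SE 0.209; n = 3 each). The ligase gene DNAlig4 rose 3.15-fold, and RpA-70 and RPA3, subunits of the single-strand binding complex RPA, rose 2.89-fold and 3.28-fold. RPA2, a further subunit of that complex, did not pass the test (log2 -0.13, edgeR adjusted p = 0.616). The actin gene Act5C fell from 2850 ± 244 to 1233 ± 229 CPM and betaTub56D from 1763 ± 126 to 849.5 ± 214 CPM, while shot, a linker of actin and microtubules, rose 3.47-fold. Of 17 cytoskeleton and adhesion genes 2 rose and 4 fell, and adjusted over the list alone 2 were higher and 5 lower. As a set the list passed neither camera (adjusted p = 0.214) nor fry (adjusted p = 0.284). In the edgeR test 2049 of 11590 genes passed an adjusted p of 0.05, 933 higher and 1116 lower, of which 645 and 540 changed at least 2-fold. Of the tested genes 41.8% had no overlap between groups. The mean of that share over the 10 divisions of the 6 libraries into 3 and 3 is 10%. Genes vary together, so a division can lie above that mean without an effect, and the shares of the other divisions were not computed. RPA3 lost its call without control replicate 1 (adjusted p = 0.0501), and betaTub56D without control replicate 2 or knockdown replicate 1 or 3 (0.0573, 0.0519 and 0.0644). The count fell to 693 (412 higher and 281 lower) without control replicate 1, 903 without control replicate 2, 629 without knockdown replicate 1 and 768 without knockdown replicate 3. With total counts as the only scaling, log2 fold changes of genes shifted by a median of -0.34 and the split became 573 higher and 2788 lower; with upper quartile scaling it was 1227 higher and 809 lower. Against a log2 fold change of 1 (glmTreat) 86 genes were higher and 8 lower. With a replicate block for the possible pairing 1311 were higher and 1655 lower.

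Among called genes with a mean of at least 5 CPM, no overlap between groups and a proper symbol, the largest increases were in Tsp42Eg, Ugt302K1, insc, GstD5, bark, sr, bowl, Tie, hwt, hiro, Ndae1 and Fuca. The glutathione S-transferase gene GstD5 rose from 16.2 ± 3.66 to 219.2 ± 117 CPM (log2 3.76, SE 0.441, adjusted p = 0.00461). The transcription factor gene sr rose 11.1-fold and the receptor tyrosine kinase gene Tie 8.89-fold. Tsp42Eg, a tetraspanin gene, was at 0.299 ± 0.173 CPM in control libraries and 11.98 ± 9.2 CPM in knockdown libraries. Under the other conditions but without that on symbols, CG8620 rose most, from 3.08 ± 0.855 to 250.8 ± 113 CPM (log2 6.35, SE 0.454). Fuca lost its call without any 1 of the 3 control libraries, with adjusted p of 0.0792, 0.0891 and 0.0524 without control replicate 1, 2 and 3, and Ndae1 without control replicate 2 or 3 or knockdown replicate 1 or 3, with adjusted p of 0.0566 to 0.105. With no filter both lost it (0.0501 and 0.0652).

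Under the conditions used for the increases, the largest decreases were in Sirup, CAH7, LRP1, Ser, Pxn, Tina-1, MtnA, Ids, Spn77Ba, fok, Reck and aos, and, without the symbol condition, CG42245. The Notch ligand gene Ser fell from 53.1 ± 8.65 to 7.68 ± 2.42 CPM (log2 -2.79, SE 0.249, adjusted p = 0.00268). Pxn, which encodes the matrix peroxidase peroxidasin and is a hemocyte marker, fell from 9.09 ± 1.98 to 1.35 ± 0.439 CPM. The metallothionein gene MtnA fell from 66.5 ± 38.9 to 10.5 ± 1.35 CPM, and aos, an inhibitor of the EGF receptor, from 497.6 ± 77.7 to 102.2 ± 72.7 CPM. Sirup fell from 927.4 ± 586 to 40.6 ± 34.5 CPM and lost its call without control replicate 1 (adjusted p = 0.0501) or knockdown replicate 1 (adjusted p = 0.0638). MtnA lost it without knockdown replicate 1 (adjusted p = 0.0502). The calls of fok, aos and CG42245 were each lost without any of 4 libraries (control replicates 1 and 2 in each case), with adjusted p of 0.0531 to 0.133, and with no filter (0.0777, 0.0756 and 0.0669), and those of Tina-1 and Reck without control replicate 1 or 2 or knockdown replicate 3, with adjusted p of 0.0511 to 0.0658.

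**Figure D2:**
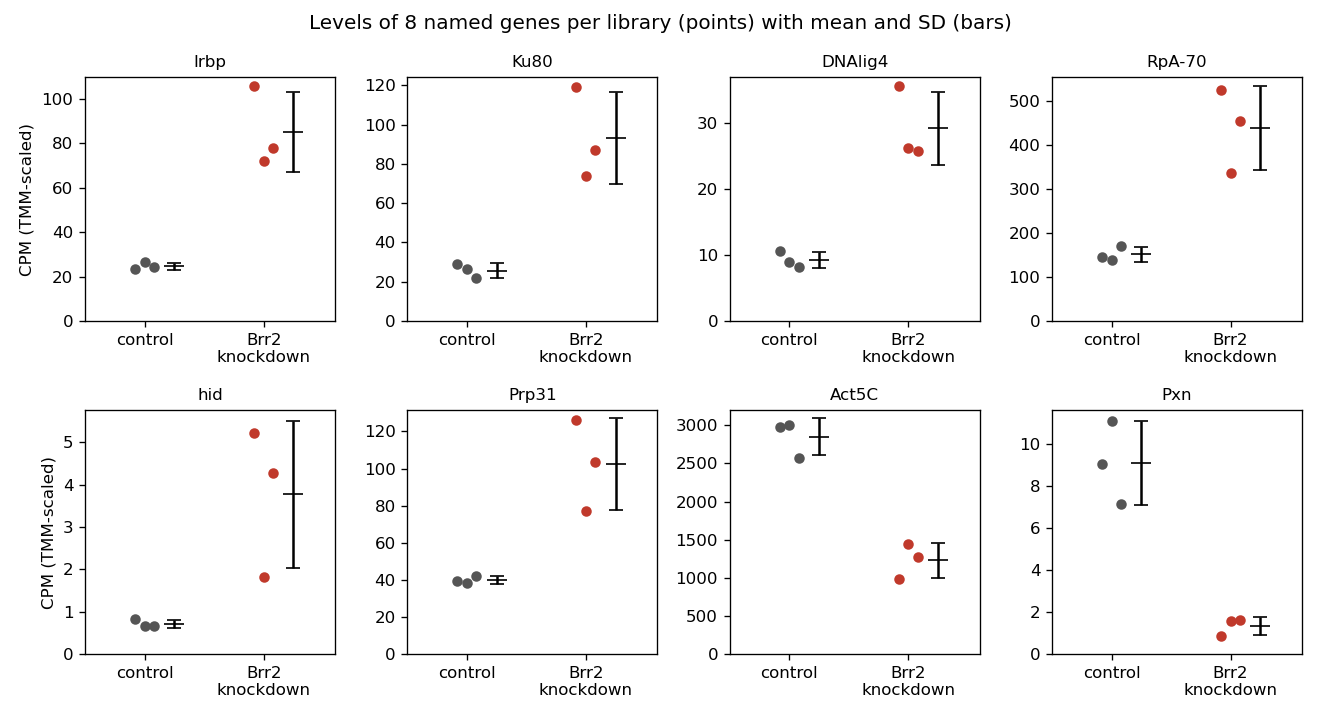
Levels in CPM (vertical axes, each from 0) of 8 genes in each library (points), with mean and SD of each group (bars). Irbp, Ku80, DNAlig4, RpA-70, hid and Prp31 are higher in the 3 knockdown libraries than in the 3 control libraries, and Act5C and Pxn are lower.

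Among spliceosome genes, 3 of 11 measured U5 and tri-snRNP genes rose and 0 fell. Prp31 rose 2.56-fold (log2 1.36, SE 0.188), CG6841 2.36-fold and CG6686 2.35-fold, each with an edgeR adjusted p of at most 0.00698. The others, Prp3, Prp38, U4-U6-60K, Prp8, Dim1, CG3436, hoip and CG4849, did not pass the test, with log2 fold changes from -0.37 to 0.47; Prp8, which holds the centre of the U5 snRNP, was at 382.6 ± 45.7 CPM in control and 460.5 ± 20.4 CPM in knockdown libraries. Adjusted over the list alone, 3 were higher, and the list as a set had camera adjusted p = 0.142, and 0.0407 without control replicate 3. In other spliceosome lists no gene rose. Of 16 U1, U2 and branch site genes 2 fell, and of 5 exon junction complex genes 1 fell. Of 12 Prp19 complex and late spliceosome genes and of 14 Sm, Lsm and SMN complex genes 0 passed. Of 9 genes known as hosts of circular RNAs, PlexA rose (log2 0.51, SE 0.12, adjusted p = 0.0291) and cdi fell (log2 -0.81, SE 0.188, adjusted p = 0.0289). Sarm had a log2 fold change of 0.52 (adjusted p = 0.0731), and with a replicate block for the pairing 0.54 (adjusted p = 0.0479). It was also called higher with upper quartile scaling (0.0453), DESeq2 (0.0201), the 5 CPM filter (0.0373) and protein-coding genes only (0.0487), and Prp3 with the 5 CPM filter (0.049). The others, dati, CaMKI, mbl, Haspin, stw and uex, had log2 fold changes from -0.19 to 0.62 and did not pass. Adjusted over the list alone 2 were higher and 1 lower. PlexA and cdi each lost the call without control replicate 1 or 2, or knockdown replicate 1 or 3, and PlexA also without knockdown replicate 2, with adjusted p of 0.0605 to 0.108, and with no filter (0.0506 and 0.0542). With total counts as the only scaling PlexA did not pass (adjusted p = 0.324), while CaMKI, Haspin, Prp38 and U4-U6-60K were called lower; without control replicate 3 Prp3, hoip and Sarm were called higher.

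Of 28 DNA break repair and checkpoint genes 8 rose and 1 fell, and adjusted over the list alone 8 were higher and 2 lower. As a set this list did not pass camera (median log2 0.04, adjusted p = 0.291) and passed fry (adjusted p = 0.0137). RpA-70 and RPA3 belong to the list of 29 DNA replication genes, of which 2 rose and 1 fell, as when adjusted over the list alone (median log2 -0.34, camera adjusted p = 0.194). The break repair member that fell was tefu, the fly ATM kinase (log2 -0.83, SE 0.202), which lost its call without control replicate 1 or 2 or knockdown replicate 1 or 3 (adjusted p of 0.0898 to 0.125) and with no filter (0.0639). Of 11 genes induced by p53 or irradiation 5 rose and 1 fell, the same numbers as adjusted over the list alone; Ku80 and Irbp were among those that rose and egr, a TNF ligand, fell to 0.537 of its control level. The set passed camera (adjusted p = 0.0318; adjusted p = 0.881 with an estimated correlation) and fry (adjusted p = 0.0214), and lost the camera call without control replicate 1, 2 or 3 (adjusted p of 0.054, 0.0573 and 0.0544). The call of egr was lost without knockdown replicate 1 or 3 (adjusted p of 0.0749 and 0.0663), and that of hid without control replicate 2 (adjusted p = 0.0503). The cell death gene hid rose 5.28-fold from a low level of 0.712 ± 0.0992 CPM, and Dredd, an apical caspase, fell to 0.408 of its control level.

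Of 33 mitosis genes 7 fell and 1 rose, with a median log2 fold change of -0.51; adjusted over the list alone 15 were lower and 1 higher. CycA fell to 0.542 and Grip71 to 0.533 of the control level, while the checkpoint kinase gene Bub1 rose 1.38-fold. CycA lost its call without any library but knockdown replicate 2 (adjusted p of 0.0611 to 0.0826) and with no filter (0.0563), Bub1 without any but control replicate 3 (0.0599 to 0.0855) and with total counts only (0.532), and Grip71 without control replicate 1 or knockdown replicate 1 or 3 (0.0501 to 0.0726). Of 73 mitochondrial ribosomal protein genes 11 fell and 1 rose; adjusted over the list alone 13 were lower and 2 higher. Of 69 nuclear genes of oxidative phosphorylation 8 fell and 1 rose, counts that were also those adjusted over the list alone. Over all 11590 tested genes 17.7% passed, 933 higher and 1116 lower. The shares of the mitochondrial ribosome and oxidative phosphorylation lists that passed were no larger than that. ND-30 fell to 0.302 and mRpL40 to 0.436 of the control level, whereas mRpS5 rose 1.7-fold, a call lost without any library but knockdown replicate 2 (adjusted p of 0.0576 to 0.117), with no filter (0.0619) and with total counts only (0.15). Of 13 hnRNP genes 4 fell, among them Syp and Rb97D, and adjusted over the list alone 5 were lower and 1 higher. Of 12 glycolysis genes Pgk fell and the other 11 did not pass; adjusted over the list alone 0 passed. Pgk lost its call without control replicate 1 or 2 or knockdown replicate 1 or 3 (adjusted p of 0.132 to 0.151), with upper quartile scaling (0.0611) and with no filter (0.0854), and Syp without control replicate 1 (0.0504). These 5 sets passed camera with adjusted p of 7.36e-05 (mitosis), 0.000493 (mitochondrial ribosome), 0.0409 (oxidative phosphorylation), 0.0455 (hnRNP) and 0.0221 (glycolysis), and each had adjusted p = 0.881 with an estimated correlation. The oxidative phosphorylation call was lost without control replicate 3 or knockdown replicate 2 (0.573 and 0.152), the hnRNP call without control replicate 2 or 3 or knockdown replicate 1 or 3 (0.0573 to 0.104), and the glycolysis call without control replicate 1 or 2 or knockdown replicate 3 (0.0521 to 0.0867).

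Among small RNA genes, 52 of 236 snoRNA and scaRNA genes rose and 0 fell, with a median log2 fold change of 0.89; adjusted over the list alone 60 were higher and 1 lower. Summed over the class, snoRNA genes held 822.6 ± 186 CPM in control and 1115 ± 245 CPM in knockdown libraries (SD, n = 3 each), or 0.0939% ± 0.0312 and 0.0989% ± 0.0184 of the counts. snoRNA:Psi28S-1135a rose from 1.44 ± 0.548 to 8.12 ± 1.79 CPM. Of 20 snRNA genes 3 rose, among them snRNA:U1:95Cc and snRNA:U1:82Eb, which were at 0.0958 and 0.343 CPM in control libraries, and adjusted over the list alone 6 were higher; copies of these genes share reads. Against the direction of the list, snRNA genes together held 1.48% ± 0.225 of the counts in control and 0.819% ± 0.0837 in knockdown libraries, or 13280 ± 2840 and 9189 ± 887 CPM. Most of that was snRNA:7SK, a regulator of transcription elongation chosen after its values were seen, which did not pass the test (log2 -0.55, edgeR adjusted p = 0.0905) but was called lower by DESeq2 (adjusted p = 0.0303) and with total counts only (0.00991). Both U1 genes lost their calls without control replicate 1 or 2 or knockdown replicate 1 or 3 (adjusted p of 0.088 to 0.13) and with no filter (0.0695 and 0.0794), snRNA:U1:82Eb also with limma voom (0.0772), and the snRNA list its call without control replicate 2 (0.0593). Of 111 replication-dependent histone gene copies 66 fell and 0 rose (median log2 -0.93; adjusted over the list alone 68 lower), and since these copies are nearly identical they are not 111 separate measurements. Camera gave adjusted p of 1.48e-15 (snoRNA), 0.0127 (snRNA) and 1.22e-19 (histones), each with adjusted p = 0.881 with an estimated correlation.

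In all, camera called 9 of the 43 lists, 3 higher and 6 lower, and 0 with an estimated correlation. Fry called 4, the p53, break repair, JAK-STAT and ecdysone lists, and of the 9 lists called by camera the 8 besides p53 had fry adjusted p of 0.149 to 0.518. Other ways of dividing the same 6 libraries into groups of 3 called 2 to 14 lists, and 8 of the 9 other divisions called at least 9, so the number of lists called does not set the knockdown apart. With a replicate block for the pairing the heat shock list was also called (adjusted p = 0.0373, against 0.142 without the block), although 0 of its 17 genes passed the gene test; it was called too without control replicate 3 (0.00388) or knockdown replicate 1 (0.044). The list of cytoplasmic ribosomal proteins (0 higher and 6 lower of 86 genes, camera adjusted p = 0.0953) was called without control replicate 2 (0.00487) or 3 (0.0249) or knockdown replicate 1 (0.00939), and with total counts only (0.000316). Some further lists also gained a call in single settings. Total counts as the only scaling gave 15 called lists. A minimum of 5 CPM gave 4, the mitosis, histone and snoRNA lists and, not called by the reported test, autophagy (adjusted p = 0.0423); the p53, mitochondrial ribosome, oxidative phosphorylation, hnRNP and glycolysis lists lost the call (0.0802 to 0.256), and the snRNA list had too few members left to be tested. The 34 lists that were not called included ecdysone response (5 of 13 genes higher, among them Eip78C), JAK-STAT and antiviral genes (3 of 9 higher, among them Sting; list called with total counts only, adjusted p = 0.0486), hemocyte genes (2 higher, Tep4 and He, and 4 lower of 20) and JNK targets (2 of 13 higher, among them upd3).

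Protein-coding genes with and without introns did not differ past the test. Median log2 fold changes were 0.02 for 1154 genes with no intron, -0.02 for 3136 genes with 1 to 2 introns, -0.05 for 2851 genes with 3 to 5 and -0.07 for 3025 genes with 6 or more. Genes whose longest intron was at least 5 kb had a median of -0.02 and those with shorter introns -0.05. Each class had camera adjusted p = 0.859, and adjusted p = 0.925 with an estimated correlation. The difference between genes without and with introns was 0.065 and changed sign, to -0.06, when features below 5 CPM were left out.

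Libraries of a group correlated at 0.961 to 0.977 across features (Pearson r of log2 CPM; features are not independent replicates) and libraries of different groups at 0.929 to 0.961. The first principal component held 48.8% of the variance of the 500 most variable features and the second 24.2%. On the first, control replicate 3 (-12.5) and knockdown replicate 2 (7.71) lay nearest the other group. The other control libraries were at -41.5 and -37.8 and the other knockdown libraries at 37.3 and 46.9. Control replicate 3 stood apart on the second component, at -44.6, and held 0.155% of its counts in nuclear rRNA and rRNA pseudogenes, against 9.94% to 11.3% in the other libraries. Without it, 1928 genes were called. Markers of other cell types gave no common direction: in the germline list aub rose (log2 2.03) and piwi fell (log2 -1.51), in the muscle list Mlc2 rose (log2 2.11) and Mef2 fell (log2 -0.62), and in the neuron, fat body, gut, lamellocyte and crystal cell lists 0 genes passed. The call of aub was lost without control replicate 2 or knockdown replicate 1 (adjusted p of 0.0755 and 0.0671), that of piwi without any library but control replicate 2 (0.059 to 0.0936) and with no filter (0.0545), and that of Mef2 without any library but knockdown replicate 2 (0.051 to 0.103) and with upper quartile scaling (0.0513).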

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

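The sums of transposon families and of histone types, and the fit without rRNA rows, were chosen after seeing the data; the other alternatives were set before the data were examined. The gene count was 3361 with total counts only, 3202 with DESeq2, 1258 with no filter and 94 against a log2 fold change of 1 (glmTreat), and 629 to 1928 with 1 library left out. The stricter hypothesis accounts for the count of 94 by construction. For the others the cause was not tested. Since 1928 and 1904 genes were called without control replicate 3 and knockdown replicate 2, the number of libraries alone does not account for the lower counts without the others. Control replicate 3 and knockdown replicate 2 were the libraries of their groups that lay nearest the other group on the first principal component. The replicate block gave 2966 genes and 10 lists. RPA2 aside, it changed no call of a named gene, list or histone type besides those of Sarm, the heat shock list, His2A and His2B. It gave 56 transposon families in place of 36, among them INE-1 (adjusted p = 0.0365, against 0.0525) and the P-element-like family (0.0401, against 0.0514). Lists called were 15 with total counts only, 4 with the 5 CPM filter, 4 with fry and 0 with an estimated correlation; the cause was not tested. Families called were 14 to 38 with 1 library left out. Brr2 stayed lower and past the threshold under the alternatives run for it (scalings, DESeq2, voom, filters, protein-coding genes only, no rRNA rows, the block and each library left out; not the fold threshold), with log2 fold changes of -1.29 to -0.81. The intron difference reversed to -0.059 with the 5 CPM filter. Genes that had not passed the test changed sign: with total counts only stw (-0.024), uex (-0.33), Prp8 (-0.08), hoip (-0.12) and CG4849 (-0.29), the size of the shift in scaling; with no filter uex (-0.013); and with 1 library left out Haspin (-0.199 to 0.022), CG4849 (-0.044 to 0.266), uex (-0.066 to 0.053), CG3436 (-0.236 to 0.042) and stw (-0.059 to 0.578). Of the single-gene results 1141 kept direction and side of the threshold, 111 lost the call, 15 gained it and 12 changed sign. Totals of estimated counts were high, but the values may not be counts of separate reads, so read depth is uncertain. What limits the calls was not tested.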

Other observations

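The tests of transposon families and of copia, R1 and R2 were chosen after the result was seen; those of snoRNAs, introns and other divisions of the libraries were set before. Summed over copies, the retrotransposon copia held 13.1% ± 1.39 of all counts in control and 28.2% ± 0.581 in knockdown libraries (SD, n = 3 each), a 2.74-fold rise in CPM (log2 1.45, SE 0.17, edgeR adjusted p = 0.00428). R1 and R2, which insert into the rRNA genes, rose 7.58-fold and 7.57-fold, and accord rose 9.46-fold, while pogo fell to 0.354 of its control level. Of 148 families or unnamed single elements 27 rose and 9 fell; with total counts as the only scaling 12 rose and 29 fell, with a replicate block for the pairing 56 passed, and 20, 17, 16 and 14 passed without control replicate 1, control replicate 2, knockdown replicate 1 and knockdown replicate 3. Copies may share reads, so shares of counts are uncertain. With copies summed by type, His1, His3 and His4 fell, to 0.515, 0.381 and 0.511 of the control level, while His2A and His2B did not pass (log2 -0.70 and -0.78, adjusted p = 0.144 and 0.152); with a replicate block for the pairing these had adjusted p = 0.0299 and 0.0172, and with total counts only 0.049 and 0.0544.

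For the rise of copia, genomic DNA in the knockdown libraries would add counts in step with annotated length, and INE-1, with 326% of the length of copia, gained 0.0918% as many CPM, which argues against it. Scaling does not account for the rise of copia, R1 and R2, since copia kept a log2 fold change of 1.11 with total counts only and R1 and R2 stayed past the threshold. Repeated counting over copies stays open for copia, whose copies may share reads (the median copy held 68.7% of the count of the highest, which alone gave a log2 fold change of 1.62). R1 and R2 have 1 annotated copy each, so no read could be counted at several copies of the same name. That alone does not settle it, since the treatment of reads with several hits is not given. Reads may also be shared between R1 and the related R1A1 (26 annotated copies, 4.92-fold higher, edgeR adjusted p = 0.0329). Genomic DNA stays open for R1 and R2, whose length in the genome the annotation may not give (INE-1 gained up to 5.78% as many CPM as they did). Of the other 24 families or unnamed single elements called higher 9 kept the call with total counts only. That count met the prediction for scaling. The 9 include the unnamed element RR51007, whose log2 fold change of 1.47 was near that of copia (1.45). It may share reads with copia. The median log2 fold change of the 15 that lost the call went from 0.83 to 0.49 (median SE 0.159). All 15 stayed above 0, a condition added after the values were seen. It could hardly fail, since total counts shifted genes by a median of -0.34 and the lowest of the 15 (BS3) started at 0.53. That condition therefore decides nothing, and scaling stays a possible source of these 15 calls. An effect of the knockdown on copia, R1 and R2 stays open beside these explanations.

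For the rise of snoRNA genes, better recovery of short RNAs stays open: 160 other genes of at most 300 bases had a median log2 fold change of 0.37 (95% bootstrap interval 0.18 to 0.61) against 0.89. That interval is over genes and does not measure the spread between libraries. More RNA from the introns that hold them may also contribute, since 591 transposon copies inside introns exceeded their host genes by a median of 0.38. That value met the prediction, but copies of INE-1 and of the P-element-like family tested with it outside genes were as high, a condition added after the values were seen, so the test does not separate introns from other sequence.

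If unspliced host RNA had increased, copies of these families inside introns on the host strand might have risen more than those outside genes. The medians were 0.38 over 303 copies (95% bootstrap interval 0.27 to 0.48) and 0.48 over 225 copies, while 215 copies in introns on the other strand had 0.33 (0.20 to 0.46). The first pair gave a difference of -0.10 (permutation p = 0.39, 95% bootstrap interval -0.32 to 0.15), which leaves the question open. The intervals and the permutation p are over copies, which may share reads. They do not measure the spread between libraries.

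Of the 10 divisions of the 6 libraries into 3 and 3, too few for a share under 0.05, only the real one gave as many as 2049 called genes (highest other 0) or 36 called families (highest other 0). With the real one included, 9 gave as many lists (9, highest other 14). At an unadjusted p under 0.05 in edgeR the other divisions gave 23 to 1040 genes and at most 15 families, against 4121 genes and 62 families. Each other division mixes libraries of both groups, so the group difference adds to its spread. Few genes and families were thus likely in advance, and these counts are no baseline for chance. Of the 10, 4 divisions, the real one included, part the 3 numbered pairs, and the highest among the other 3 was 0 genes, 0 families and 13 lists.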
